A study of Mus musculus with 15 samples.

How the data were processed

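Bulk RNA sequencing libraries came from mouse brain cortex taken 1 day after a controlled cortical impact, a piston injury to the exposed cortex used as a model of traumatic brain injury. Per the labels, the mice were EphA4 floxed wild type (WT) animals or floxed animals carrying a tamoxifen-inducible Cre driven by the VE-cadherin promoter, which deletes EphA4 in endothelial cells (KO). The tissue was dissociated and passed over CD45 and CD31 microbeads. The libraries come from the CD45 fraction, which holds leukocytes and microglia, and from the flow-through, which holds the cells that the beads did not retain. Libraries were made with a stranded mRNA kit and 14 PCR cycles, per the labels' protocols.

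The files hold gene counts, which are whole numbers of reads per gene that the authors deposited without normalization, in 1 table per fraction. Companion tables hold a normalized signal, which the authors made by dividing the counts of each fraction's table by DESeq2 size factors, per the file headers. Within each library the ratio of count to normalized signal was the same for every gene, with a largest range of 1.4e-14, so each table differs from its counts only by 1 factor per library. Per the submitters' processing notes, reads were trimmed with Trim Galore, checked with FastQC and aligned with STAR 2.7.9a to GRCm38. The counting tool, its strand setting and the annotation release are not given in the sources used here. Reads of genes that overlap on opposite strands may therefore not be told apart, and values of such genes are marked as uncertain. Each table lists 33223 genes, of which 33130 were matched to GENCODE M21, the GRCm38 annotation used here for names, positions, GC content and exon length. Total counts were 19204814 to 27270907 per library in the flow-through tables and 11574414 to 31337948 in the CD45 tables. Mitochondrially encoded genes took 2.58 to 4.47% of counts in the flow-through libraries and 0.75 to 1.42% in the CD45 libraries.

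Groups follow the labels: 5 flow-through WT, 3 flow-through KO, 3 CD45 WT and 4 CD45 KO libraries. Replicate numbers were given in accession order, pair nothing, and are names only. The labels do not name animals, so p-values measure the spread between these samples, which may be partly technical, and flow-through and CD45 libraries may share animals. The 18 pairs of libraries within groups differed by 9.42 to 49.8 chi-square units per degree of freedom, so none was counted as a duplicate. For 1 library the label and the table disagree. The library labelled flow-through WT replicate 5 stands in the CD45 tables and has the marker profile of the CD45 libraries. It was left out of the reported fits, which use 14 libraries. The design fixed before the data were examined included it, so this is a departure made after the data were seen. Fits that enter it as labelled, which is the design as fixed, are given beside the reported fits. Fits that place it with the CD45 WT libraries were added after the data were seen.

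Each genotype comparison was fitted within 1 fraction. The comparison of fractions and the genotype by fraction interaction used all 14 libraries with 1 mean per group. Counts were tested with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood test with robust estimation, TMM scaling and filterByExpr, which asks for at least 10 counts in enough libraries and 15 in total. P-values were adjusted by the Benjamini-Hochberg method and called at an adjusted p under 0.05. Means with an SD, and the values per library of Epha4, Abhd1, Lbp, Angpt1 and Akap12, are TMM-scaled CPM within a fraction. The other levels and ranges over libraries, those of the library left out and the figure of marker genes are CPM without TMM scaling, counts divided by the library total. Gene lists were tested with camera in limma 3.58.1, with a preset correlation between genes of 0.01, and tested again with a correlation estimated from the data and with fry. Before the data were examined, 46 lists were fixed, 18 of cell type markers and 28 of pathways. A list was tested when at least 3 members were measured. Members were counted over all genes tested and again adjusted over the list alone. Each list was also scored per library as the mean log2 CPM of its members, and scores were compared between genotypes with an exact two-sided permutation test over 35 splits, for which the smallest possible p is 0.0286.

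The genes named follow a rule fixed before the data were examined. It takes a panel (Epha4, Tek, Akap12, Angpt1, Angpt2, Cldn5, Cdh5, Pecam1 and Ptprc) and, for each genotype comparison, the 12 called genes with the largest and the 12 with the smallest log2 fold change among those with a mean log2 CPM of at least 1, a symbol that is not a predicted model and no overlap between the groups' libraries. With fewer than 10 such genes, the list was filled to 10 with the smallest p. It adds up to 4 members of each list described, the 5 genes with the smallest p in the interaction, and 8 genes per direction in the comparison of fractions at a mean log2 CPM of at least 5. Some genes that fill the rule are not reported here. Genes named outside the rule are said to have been chosen after their values were seen.

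The tests were run on simulated counts with 200 changed genes before use. The changed genes had a mean CPM of at least 1 and lay outside the gene lists, and each gene was drawn independently. The recovered shares therefore do not cover genes at lower levels. In the flow-through comparison, 65.7% of genes changed 1.5-fold, 91% of those changed 2-fold and 98.5% of those changed 4-fold were recovered over 16355 genes. In the CD45 comparison these shares were 37.3%, 55.2% and 95.5% over 15373 genes, and for the interaction 6%, 43.3% and 77.3% over 17831 genes. False calls made up 6.1% of calls in the flow-through simulation and 6% in the CD45 simulation. The alternatives were DESeq2 1.42.0, RLE and upper-quartile scaling, no count filter and a stricter filter (CPM above 1 in every library of a group), limma-voom with quality weights, limma on log2 of the normalized signal plus 1, an adjusted p under 0.1, all 15 libraries in 1 fit, and each library left out in turn. Alternatives added after the data were seen were the placement of the library with the disagreeing label among the CD45 WT libraries, 14 libraries in 1 fit, a term for or removal of 2 CD45 libraries that stood apart, and removal of each library's trend on GC content and exon length.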

Results

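The data are 15 libraries of bulk RNA from mouse cortex 1 day after controlled cortical impact, in WT mice and in mice lacking EphA4 in endothelial cells. The question, as the series title states it, is how endothelial EphA4 acts on Tie2 and Akap12 signalling and the blood-brain barrier after brain injury. The libraries come from a pair of cell fractions of the dissociated tissue, the CD45 fraction and the flow-through left by CD45 and CD31 beads. The comparisons used 4 WT and 3 KO flow-through libraries and 3 WT and 4 KO CD45 libraries. Total counts per library ran from 11574414 to 31337948. Ddx3y, a Y-linked gene, lay between 75.9 and 151 CPM in the 14 libraries, and Xist, which silences the X chromosome in females, did not exceed 0.417 CPM, so no library had a female profile.

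Epha4, the targeted receptor tyrosine kinase, was measured first in every library. It spans positions 77367185 to 77515088 on the minus strand of chromosome 1 in GRCm38. In the flow-through it averaged 41.2 CPM ± 2.89 (SD, n = 4) in WT and 39.3 CPM ± 2.75 (SD, n = 3) in KO libraries, a log2 fold change of -0.07 (SE 0.09, edgeR adjusted p = 0.849). In the CD45 fraction it averaged 2.83 CPM ± 0.133 (SD, n = 3) in WT and 2.52 CPM ± 0.949 (SD, n = 4) in KO libraries, with a log2 fold change of -0.17 (SE 0.31, edgeR adjusted p = 0.989). Neither fraction is an endothelial isolate. Most Epha4 counts here can come from other cells, so these values do not check the endothelial deletion.

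The first comparison asks what the bead separation retained. The CD45 libraries held the markers of leukocytes and microglia at high levels. Ptprc, which encodes CD45, was 10.45 log2 units higher in the CD45 libraries (SE 0.13, edgeR adjusted p = 3.21e-18, n = 7 per fraction). Lyz2, the lysozyme of myeloid cells, lay at 2220 to 5540 CPM in CD45 libraries and 1.17 to 3.11 CPM in the flow-through, a log2 fold change of 11.52 (SE 0.33). The chemokine gene Ccl6 was higher by 11.65 (SE 0.20). The 6 other genes with the largest increases were Chil3 (12.44), Ms4a4a (12.33), Ccr2 (11.96), Napsa (11.84), Cd177 (11.63) and Il7r (11.52), and because none of them passed 7 counts in a flow-through library, their fitted folds are imprecise. Genes of the cells that pass the beads were lower in the CD45 libraries. These included Fa2h (-6.64, SE 0.12), an enzyme of myelin lipid synthesis, Gpr37 (-6.64, SE 0.14), Olig1 (-6.61, SE 0.15), a transcription factor of the oligodendrocyte lineage, and the potassium channel gene Kcna1 (-6.68, SE 0.18). The neuroblast genes Dlx6os1 (-7.52, SE 0.18), Dcx (-7.23, SE 0.25) and Dlx1 (-6.73, SE 0.28) and the gene Soga3 (-6.62, SE 0.12) completed the largest decreases. Exons of Napsa, Olig1, Dlx1, Dlx6os1 and Soga3 overlap other genes, and their values are uncertain.

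By list, all 16 members measured for infiltrating monocytes and macrophages, all 20 for neutrophils and all 10 for border-associated macrophages were higher in the CD45 libraries, with median log2 fold changes of 10.61, 10.25 and 9.66. Of 14 homeostatic microglia genes 12 were higher and 1 lower (median 7.84). All 16 astrocyte genes (median -5.60) and all 14 oligodendrocyte genes (median -5.97) were lower. All 18 neuron genes were lower (median -2.47). Of 24 endothelial genes 23 were higher in the CD45 libraries, with a median of 3.42, and counts adjusted over the list alone were the same. Pecam1, which encodes CD31, was higher by 5.72 (SE 0.27), Tek, the Tie2 receptor, by 3.77 (SE 0.31), Angpt2 by 2.32 (SE 0.20), the tight junction gene Cldn5 by 2.54 (SE 0.15) and Cdh5 by 1.10 (SE 0.19). Akap12, a scaffold of protein kinase A, was lower in the CD45 libraries by a log2 fold change of -1.17 (SE 0.13), as were Angpt1, the Tie2 ligand (-3.37, SE 0.20), and Epha4 (-3.38, SE 0.14), Angpt1 being uncertain because its exons overlap another gene. Each of these panel genes passed the edgeR test. The test called 15583 of 18098 genes, 7492 higher and 8091 lower. Camera called 33 of 46 lists, 24 up and 9 down, and 15 of them held with an estimated correlation, among them homeostatic microglia, monocytes and macrophages, astrocytes and oligodendrocytes. The endothelial call (adjusted p = 0.000818) was lost, with adjusted p = 0.44 with an estimated correlation, as were those of neutrophils (adjusted p = 0.136 with an estimated correlation) and neurons (0.532 in the same test). Upper-quartile scaling shifted the median log2 fold change of all genes by -0.252.

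**Figure D1:**
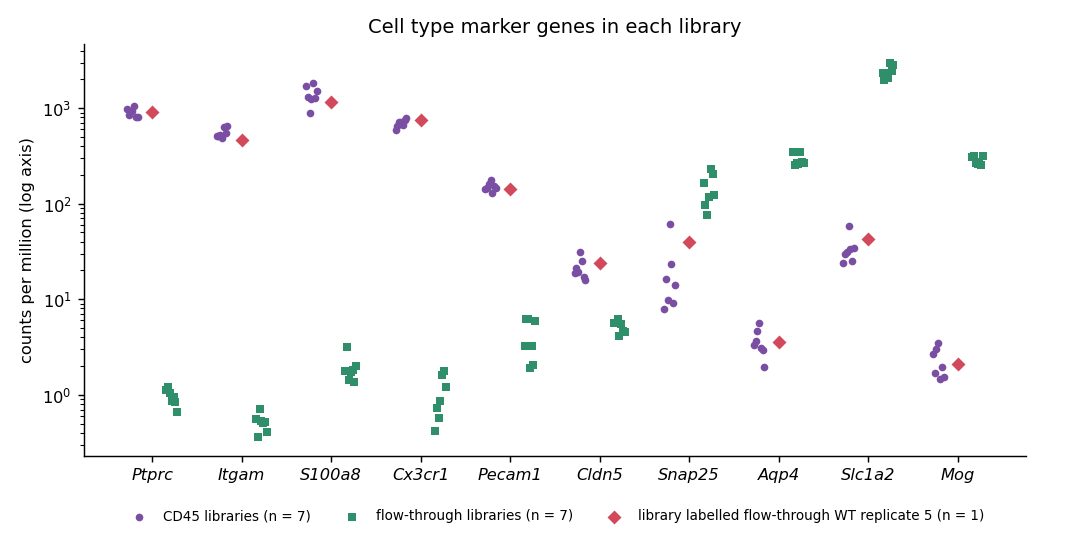
CPM of 10 marker genes (log axis) in each library, with CD45 libraries as circles, flow-through libraries as squares and the library labelled flow-through WT replicate 5 as a diamond. That library lies with the CD45 libraries, with Ptprc at 906 CPM.

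The second comparison asks what endothelial loss of EphA4 did in the cells left in the flow-through. Several genes of neurons were higher in the KO libraries. Hs3st2, a heparan sulfate sulfotransferase expressed in brain, averaged 4.57 CPM ± 0.928 (SD, n = 3) in KO and 1.15 CPM ± 0.309 (SD, n = 4) in WT libraries, a log2 fold change of 1.98 (SE 0.25, edgeR adjusted p = 0.00126), uncertain in that its exons overlap a gene on the opposite strand. Kcnj4, an inward rectifier potassium channel, rose from 2.7 CPM ± 0.160 (SD, n = 4) to 8.74 CPM ± 1.83 (SD, n = 3), a log2 fold change of 1.69 (SE 0.18, edgeR adjusted p = 0.000518). Slc17a7, the vesicular glutamate transporter of excitatory neurons, averaged 93.4 CPM ± 10.6 (SD, n = 3) in KO and 40.8 CPM ± 12.7 in WT libraries (log2 fold change 1.19, SE 0.21, edgeR adjusted p = 0.0343), and passed in 9 of 18 alternative settings. A smaller set of genes was lower, among them Sorcs2, a sorting receptor that binds neurotrophin precursors, at 67.2 CPM ± 5.25 in KO and 119 CPM ± 9.11 in WT libraries (log2 fold change -0.83, SE 0.09, edgeR adjusted p = 0.000551).

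The edgeR test called 260 of 16546 genes, 235 higher and 25 lower in KO, with a median absolute log2 fold change of 0.80. In each of the 260 the KO libraries lay all above or all below the WT libraries. Over all genes tested, 11.5% were separated in this way, against 5.7% by chance. The other genes with the largest increases were the immediate early transcription factor Egr4 (1.69, SE 0.24), the synaptic genes Rims4 (1.69, SE 0.21), Iqsec3 (1.47, SE 0.19) and Cplx3 (1.37, SE 0.24), Rprml (1.58, SE 0.23), the neuropeptide receptor Vipr1 (1.53, SE 0.21), the dendritic protein gene Ddn (1.57, SE 0.24), the channel gene Panx2 (1.38, SE 0.15), the kinesin Kifc2 (1.38, SE 0.14) and Rell2 (1.37, SE 0.16). Ddn passed in 10 of the 18 alternative settings. Exons of Ddn, Kifc2 and Rell2 overlap those of a neighbouring gene, so their values are uncertain. The largest decreases, after the rule, included those of the cytokine gene Il19 (-1.13, SE 0.23, adjusted p = 0.0226, past the threshold in 10 of 18 alternative settings), Cfap300 (-0.84, SE 0.18, past it in 11), Sorcs2, the oxysterol hydroxylase Cyp7b1 (-0.72, SE 0.15, past it in 11), Abhd1 (-0.68, SE 0.12), the death receptor Fas (-0.67, SE 0.12), the membrane repair gene Dysf (-0.63, SE 0.12), the imprinted RNA H19 (-0.59, SE 0.11), the adhesion gene Chl1 (-0.58, SE 0.10) and the transglutaminase Tgm1 (-0.57, SE 0.10). Of the exon sequence of Abhd1, 89.6% overlaps Preb on the opposite strand, and exons of Dysf, H19 and Tgm1 also overlap other genes, so these values are likewise uncertain. The genes higher in KO had a median GC content of 56.9%, against 49.6% for all genes tested, and the counts of flow-through KO replicate 3 tilted toward GC-rich genes more than those of the other flow-through libraries. With each library's GC and length trend removed, 191 genes were called.

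**Figure D2:**
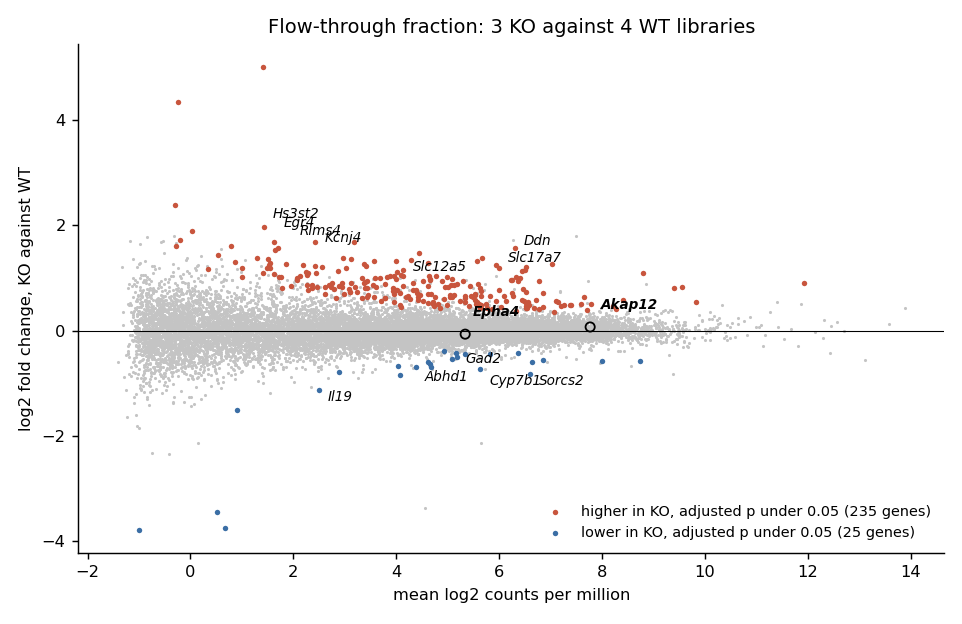
Log2 fold change of KO against WT (vertical axis) over mean log2 CPM (horizontal axis) for 16546 genes in the flow-through, from 3 KO and 4 WT libraries. Coloured points passed the edgeR test, 235 higher and 25 lower in KO, and Epha4 and Akap12 (open circles) lie near 0.

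Of 18 neuron genes measured, 5 rose, 1 fell and 12 did not pass, and adjusted over the list alone 12 were higher and 1 lower. Besides Slc17a7, Slc12a5, the neuronal chloride exporter, rose by 1.03 (SE 0.14, adjusted p = 0.00166), the NMDA receptor subunit Grin1 by 0.85 (SE 0.13, adjusted p = 0.0057) and the synaptic vesicle gene Syn1 by 0.58 (SE 0.11, adjusted p = 0.0134, past the threshold in 10 of 18 alternative settings), all by edgeR. Nrgn, a postsynaptic calmodulin-binding protein (1.22, SE 0.22, edgeR adjusted p = 0.0418), rose and Gad2, which makes GABA (-0.42, SE 0.10, edgeR adjusted p = 0.0494), fell, both named after their values were seen. Exons of Grin1 and, over a few bases, Syn1 overlap other genes, which makes their values uncertain. The list had a median log2 fold change of 0.65 and a camera adjusted p of 3.58e-15, or adjusted p = 0.475 with an estimated correlation. Its score per library was 0.59 log2 units higher in KO, with no overlap between genotypes (exact two-sided permutation p = 0.0286, adjusted over 44 lists 0.21). Glutamate and GABA receptor genes were also called upward as a list (median 0.15, camera adjusted p = 0.000111, adjusted p = 0.477 with an estimated correlation). Grin1 and Gabbr2, a subunit of the GABA-B receptor (0.75, SE 0.13, adjusted p = 0.0116), rose, and the other 14 did not pass. Adjusted over the list alone 5 were higher. Nuclear genes of oxidative phosphorylation (median 0.11, adjusted p = 0.00602), oligodendrocyte precursor genes (median 0.19, adjusted p = 0.0109) and anti-inflammatory and repair macrophage genes (median 0.33, adjusted p = 0.0338) were called upward with no member passing over all genes. Adjusted over the list alone, 2, 1 and 0 of their members were higher, and with an estimated correlation their adjusted p values were 0.971, 0.477 and 0.477.

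4 lists were called downward by camera. Reactive astrocyte genes had a median of -0.17 (adjusted p = 0.00138), with 18 of 24 members negative, and adjusted p = 0.475 with an estimated correlation. Only Cd109, a cell surface glycoprotein, fell among them (-0.56, SE 0.12, edgeR adjusted p = 0.0349, past the threshold in 9 of 18 alternative settings), also when adjusted over the list alone. Cell cycle genes had a median of -0.15 (adjusted p = 0.00193, adjusted p = 0.896 with an estimated correlation) with no member passing, the lowest p being that of Ccnb1 (-0.45, SE 0.12, edgeR adjusted p = 0.117). Endothelial genes had a median of -0.32 (adjusted p = 0.0042, adjusted p = 0.72 with an estimated correlation), with 19 of 21 negative, 0 passing in edgeR over all genes and 2 lower adjusted over the list alone, Ly6c1 (-1.18, SE 0.31) and Ly6a (-0.65, SE 0.16) having the smallest p. The endothelial score varied within genotypes, and its test did not pass (-0.40, exact two-sided permutation p = 0.286). Immediate early and dissociation stress genes had a median of -0.17 (adjusted p = 0.0201, adjusted p = 0.896 with an estimated correlation), led by Btg2 (-0.38, SE 0.09, edgeR adjusted p = 0.0719), and 1 member was lower adjusted over the list alone. None of the 9 calls held with an estimated correlation. Fry called 0 of 44 lists, and its mixed test, which ignores direction, called 6. Of the 44 list scores, 8 parted the genotypes without overlap, against 5.7% by chance, and 6 had an exact permutation p under 0.05, with a smallest adjusted p of 0.21. These 6 were neurons, oligodendrocyte precursors, dendritic cells, Eph receptors and ephrins, anti-inflammatory and repair macrophage genes, and glutamate and GABA receptors. Homeostatic microglia (KO minus WT 0.41) and reactive astrocyte genes (-0.16) also parted the genotypes, each with an exact two-sided permutation p of 0.0571. Only 4 dendritic cell genes were measured, and Ptprc did not exceed 1.22 CPM in the flow-through. The scores of the dendritic cell and macrophage lists therefore do not show immune cells there. They do not exclude a small residue of myeloid RNA that differs between genotypes.

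**Figure D3:**
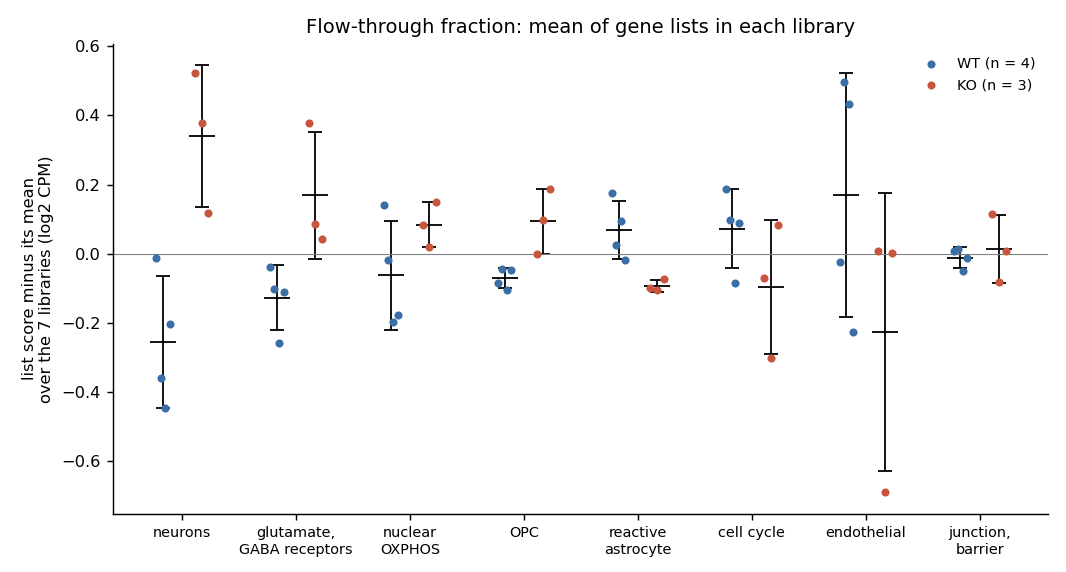
Mean log2 CPM of 8 gene lists in each flow-through library, less the mean over the 7 libraries, with WT (n = 4) and KO (n = 3) libraries as points and the group mean ± SD as bars. All 3 KO libraries lie above the 4 WT libraries for neurons, and the genotypes overlap for endothelial genes.

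Genes of the Tie2 pathway and the barrier did not pass the test in the flow-through. CD31 beads act on endothelial cells, and the flow-through held little RNA of endothelial genes. Cldn5 lay at 4.11 to 6.19 CPM and Pecam1 at 1.91 to 6.23 CPM in its 7 libraries. The values below therefore do not test these genes in endothelial cells. Tek averaged 0.863 CPM ± 0.295 in KO and 1.36 CPM ± 0.450 in WT libraries (log2 fold change -0.62, SE 0.34, edgeR adjusted p = 0.559). Akap12 averaged 224 CPM ± 29.5 in KO and 213 CPM ± 20.4 in WT libraries (0.07, SE 0.11, edgeR adjusted p = 0.871). Angpt1 (-0.30, SE 0.20), Angpt2 (0.02, SE 0.21), Cldn5 (-0.11, SE 0.19), Cdh5 (0.28, SE 0.21), Pecam1 (-0.18, SE 0.48) and Ptprc (-0.36, SE 0.30) did not pass either. Camera did not call Tie2 and angiopoietin signalling (median -0.11, adjusted p = 0.091, 1 of 18 members lower adjusted over the list alone) or junction and barrier genes (median -0.04, adjusted p = 0.985). Of 21 Eph receptor and ephrin genes only Ephb6 rose (0.70, SE 0.13, edgeR adjusted p = 0.0142), 3 were higher adjusted over the list alone, and the list was not called (adjusted p = 0.114). The microglial genes Cx3cr1 (1.25, SE 0.31, adjusted p = 0.0723) and Csf1r (1.11, SE 0.28, adjusted p = 0.0781) were at low levels in the flow-through and did not pass. Exons of Angpt1, Cx3cr1 and Csf1r overlap other genes, so their values are uncertain. Cx3cr1 and Csf1r passed when adjusted over the list of homeostatic microglia alone, and camera did not call that list (adjusted p = 0.145).

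The number of genes called depended on the libraries and the fit. Leaving out flow-through KO replicate 1, KO replicate 2, WT replicate 2 or WT replicate 3 gave 134, 163, 144 and 159 genes. With the library labelled flow-through WT replicate 5 entered as labelled, as the fixed design had it, 0 genes were called. A joint fit of the 14 libraries gave 30.

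**Figure D4:**
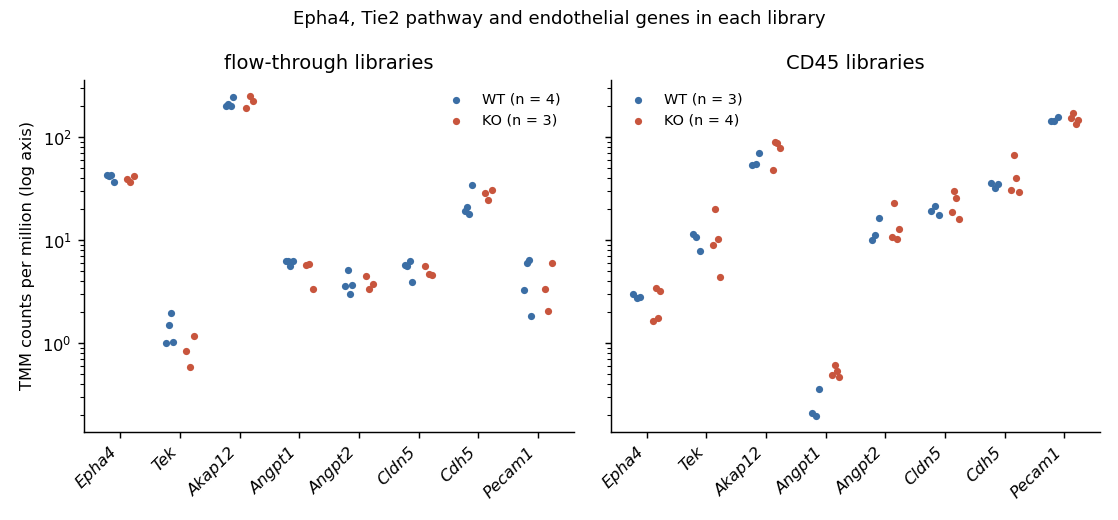
TMM-scaled CPM (log axis) of Epha4, Tie2 pathway genes and endothelial genes in each flow-through (left) and CD45 (right) library, WT and KO. No gene shown passed the edgeR test between genotypes, and Epha4 in the flow-through lies between 36.7 and 43.0 CPM.

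The third comparison asks whether loss of endothelial EphA4 changed the immune cells of the injured cortex. No single gene of the CD45 fraction passed the test. Within the naming rule the gene with the smallest p was Slc7a5, an amino acid transporter subunit, at 77.0 CPM ± 6.10 (SD, n = 4) in KO and 112 CPM ± 4.30 (SD, n = 3) in WT libraries, a log2 fold change of -0.54 (SE 0.09, edgeR adjusted p = 0.775). Lrg1, a secreted glycoprotein, followed with 369 CPM ± 33.4 in KO and 535 CPM ± 31.7 in WT libraries (-0.54, SE 0.10, edgeR adjusted p = 0.974). Ptprc was at 919 CPM ± 107 in KO and 893 CPM ± 93.7 in WT libraries.

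The other genes that filled the rule had an edgeR adjusted p of 0.974 each. They were Slc43a3 (-0.99, SE 0.19), Lbp, which binds bacterial lipopolysaccharide (-0.83, SE 0.17), Abhd1 (-0.64, SE 0.13), Ptger2, a prostaglandin receptor (-0.53, SE 0.12), Soat2 (-0.52, SE 0.11), Sema6b (-0.46, SE 0.09), Sema3c (0.57, SE 0.13) and Rbpj, the Notch transcription factor (0.71, SE 0.16). Exons of Abhd1, Ptger2 and Angpt1 overlap other genes, and their values are uncertain. EdgeR called 0 of 15660 genes, with 693 genes (4.4%) at an unadjusted p under 0.05. The smallest p of all was that of 1110059E24Rik (0.72, SE 0.12, edgeR adjusted p = 0.775), named after its values were seen. DESeq2 called 10 genes, 1 higher (1110059E24Rik) and 9 lower, among them Slc7a5, Lrg1, Slc43a3, Sema6b, Lbp, Abhd1 and Soat2, and limma-voom called 0. Without CD45 KO replicate 1, edgeR called 1 gene, Lbp (-1.05, SE 0.10, adjusted p = 0.0457). In the panel, Tek (0.13, SE 0.43), Akap12 (0.35, SE 0.21), Angpt2 (0.18, SE 0.30), Cldn5 (0.23, SE 0.21), Cdh5 (0.28, SE 0.27) and Pecam1 (0.04, SE 0.10) did not pass. Angpt1, at 0.526 CPM ± 0.0647 in KO and 0.254 CPM ± 0.0890 in WT libraries, did not pass either (1.03, SE 0.44, edgeR adjusted p = 0.974). The CD45 fraction is not an endothelial isolate, so these panel values do not test the genes in endothelial cells.

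Camera called 11 of 46 lists in the CD45 fraction, 8 up and 3 down, none of which held with an estimated correlation. In none of the 11 did a member pass in edgeR, over all genes or adjusted over the list alone. Infiltrating monocyte and macrophage genes were called upward (median 0.15, adjusted p = 0.0161, adjusted p = 0.873 with an estimated correlation), with 15 of 16 positive and Chil3 (0.46, SE 0.16) and Ms4a4c (0.66, SE 0.47, uncertain because its exons overlap another gene) among them. Pro-inflammatory cytokine genes were called upward (median 0.15, adjusted p = 0.0235, adjusted p = 0.71 with an estimated correlation). Among them Il6, at 22.7 CPM ± 4.83 in KO and 15.3 CPM ± 1.89 in WT libraries, had a log2 fold change of 0.57 (SE 0.17), Ptgs2, which encodes cyclooxygenase 2, 0.54 (SE 0.20) and Csf3 0.74 (SE 0.29). Homeostatic microglia genes were called upward (median 0.12, adjusted p = 0.0395), with Siglech at 0.38 (SE 0.14) and Tmem119 at 0.35 (SE 0.14), and disease-associated microglia genes downward (median -0.13, adjusted p = 0.0395), with Itgax at -0.55 (SE 0.15) and Lpl at -0.44 (SE 0.17). Both had an adjusted p = 0.71 with an estimated correlation. Neutrophil genes were called downward (median -0.19, adjusted p = 0.023, adjusted p = 0.984 with an estimated correlation), with Csf3r at -0.36 (SE 0.16). Genes of iron and haem handling were called downward (median -0.13, adjusted p = 0.0235, adjusted p = 0.71 with an estimated correlation) and were the only list that fry also called (adjusted p = 0.0367). Their score was lower in each of the 4 KO libraries than in the 3 WT libraries (-0.16, exact two-sided permutation p = 0.0571). Cholesterol synthesis genes were called upward (median 0.14, adjusted p = 0.0205, adjusted p = 0.758 with an estimated correlation), led by Msmo1 (0.31, SE 0.09).

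The remaining upward calls were lists of non-immune or mitochondrial transcripts. They were neurons (median 0.88, camera adjusted p = 2.12e-07), glutamate and GABA receptors (median 0.82, adjusted p = 2.26e-06), mitochondrially encoded genes (median 0.36, adjusted p = 2.26e-06) and astrocytes (median 0.22, adjusted p = 0.0205). With an estimated correlation their adjusted p values were 0.758, 0.71, 0.71 and 0.957. Grin2a (1.72, SE 0.54) and Rbfox3 (1.46, SE 0.52) had the smallest p of the receptor and neuron lists. The neuron score overlapped between genotypes (0.75 higher in KO, exact two-sided permutation p = 0.286), with a KO SD of 0.88 log2 units. It was highest in CD45 KO replicate 2, as were the scores of the other 3 lists. In CD45 KO vs WT without that library the astrocyte call was lost (adjusted p = 0.248), while neurons (adjusted p = 0.00131), glutamate and GABA receptors and mitochondrially encoded genes (adjusted p = 0.000716 each) were still called with the preset correlation. Type I interferon genes (median 0.17, adjusted p = 0.0692), chemokines (median 0.13, adjusted p = 0.171), T and NK cells (median 0.10, adjusted p = 0.43) and endothelial cells (median 0.06, adjusted p = 0.962) were not called. Of the list scores, 0 of 46 had an exact permutation p under 0.05. CD45 WT replicate 3 and CD45 KO replicate 4 stood apart on the first principal component, which held 29% of the variance.

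**Figure D5:**
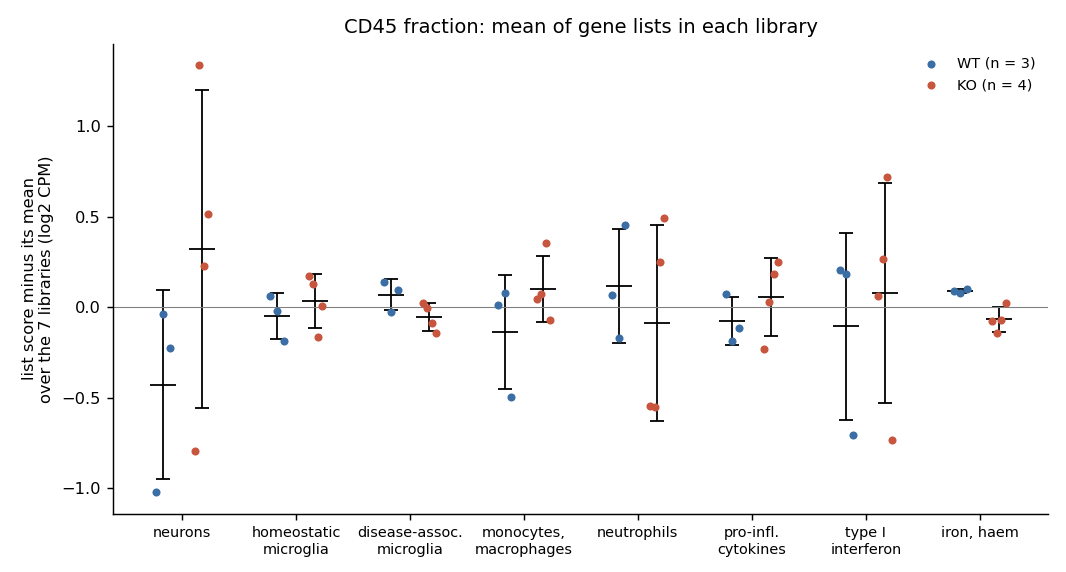
Mean log2 CPM of 8 gene lists in each CD45 library, less the mean over the 7 libraries, with WT (n = 3) and KO (n = 4) libraries as points and the group mean ± SD as bars. The genotypes overlap in each list shown except iron and haem handling, where the 4 KO libraries lie below the 3 WT libraries.

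The last comparison asks whether the genotype difference itself differed between the fractions. The gene with the smallest p was Rab15, a small GTPase of endosomal recycling. It rose in the KO flow-through libraries (log2 fold change 1.29, SE 0.14, edgeR adjusted p = 0.000615) and had a log2 fold change of -0.63 in the CD45 libraries (SE 0.23, edgeR adjusted p = 0.974), an interaction of -1.94 (SE 0.29, edgeR adjusted p = 0.131). Ypel3 (-1.01, SE 0.19), Palm (-0.73, SE 0.13), Tbc1d9b (-0.70, SE 0.13) and R3hdm4 (-0.69, SE 0.12) followed, each with an edgeR adjusted p of 0.178. Exons of R3hdm4 and Kcnab2 overlap other genes, and their values are uncertain. EdgeR called 0 of 18098 genes, with 1305 genes at an unadjusted p under 0.05, while DESeq2 called 46, 4 up and 42 down, and limma-voom 4, which were Rab15, R3hdm4 and, named after their values were seen, Kcnab2 and Ppp1r9b. Without a count filter edgeR called 15 genes. Camera called 3 of 46 lists. Anti-inflammatory and repair macrophage genes had an interaction median of -0.22 (adjusted p = 0.025, adjusted p = 0.225 with an estimated correlation), reactive astrocyte genes 0.19 (adjusted p = 0.025, adjusted p = 0.405 with an estimated correlation), and glutamate and GABA receptor genes 0.57 (adjusted p = 0.0326, adjusted p = 0.935 with an estimated correlation). No member of the 3 lists passed in edgeR, over all genes or adjusted over the list alone. Neither the neuron list (median 0.40, adjusted p = 0.589) nor the endothelial list (median 0.43, adjusted p = 0.0629) was called in the interaction. Without CD45 KO replicate 2 no list was called.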

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

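All tests of explanations in this part were chosen after the result was seen. The criterion for the counts over other splits of the samples was also written afterwards. The fixed design holds no split count and no search for outlying libraries. It does hold the interaction test for differing fractions.

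The library labelled flow-through WT replicate 5 was left out of the comparisons and held a strong signal, with Ptprc at 906 CPM against 0.660 to 1.22 CPM in the 7 flow-through libraries. Of the 16 genes that differed most between the fractions, 12 lay within the range of the CD45 libraries in it and 0 within that of the flow-through libraries. Its Spearman correlation across genes, which are not independent replicates, was 0.984 to 0.991 with the CD45 libraries and 0.702 to 0.709 with the flow-through libraries. A flow-through library mixed with CD45 cells would keep much of its oligodendrocyte RNA, and the 13 oligodendrocyte genes compared had a median of 1.6% of their flow-through medians and at most 6.44%, which argues against a mixture. A CD45 library with a wrong label could give these values. Its genotype was not tested, and no biological explanation was tested.

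The 235 genes higher in the flow-through KO libraries were the main difference between the genotypes. Removing each library's trend on GC content and exon length moved their median log2 fold change from 0.82 to 0.73, with an interquartile range of 0.53 to 0.98, and 143 still passed, which argues against such a trend as the whole cause. A larger share of all neurons alike would raise neuroblast genes too. Their score had a 95% interval reaching 0 and did not pass (median -0.36 over 12 genes, none past the threshold, exact permutation p = 0.0857). The neuron score, 0.59 higher in KO, less the neuroblast score was 0.97 higher in KO (exact permutation p = 0.0286). That argues against a rise of both alike. A smaller share of the most abundant cells would raise endothelial genes. Their score had a 95% interval up to 0.41 and did not pass (median -0.32, exact permutation p = 0.286). Its comparison with 0.59 leaves out the spread of the neuron score, and CD31 beads act on endothelial cells, so it cannot decide. In the CD45 fraction 179 of 218 of the same genes were positive (median 0.45), but the test of their score did not pass (exact two-sided permutation p = 0.257), so neuron RNA carried into both fractions of KO samples cannot be told apart from chance with 3 and 4 libraries. A smaller share of the most abundant cells stays open. Also open is a hypothesis that mature neurons, or their debris, made up more of the KO flow-through. That may reflect better survival of neurons, dissection or dissociation, and none of these 3 was tested.

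Of the 25 genes lower in the flow-through KO libraries, 14 of the 21 measured in the CD45 fraction were also negative there, with a median of -0.18. Abhd1 lay at 13.1 to 17.1 CPM in KO and 22.8 to 27 CPM in WT flow-through libraries, and at 6.80 to 7.86 CPM in KO and 10.9 to 11.9 CPM in WT CD45 libraries, counts that are uncertain because most of its exons overlap Preb. A strain or linked variant that acts in both fractions could give such a pattern, but the test of the score of the 21 genes in the CD45 fraction did not pass (exact two-sided permutation p = 0.114), which leaves it open. Of 10000 random gene sets of the same size, a share of 0.37 held as many neighbouring genes within 1 Mb as the 25 do. Clustering at that distance cannot be told apart from chance. The count misses genes further apart, so it cannot decide on a longer shared chromosome segment. Endothelial loss of EphA4 itself, which the design names, was not separated from these explanations.

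Of 72 groups of values searched, 3 held a library far from the others, about as many as the 1 in 20 that chance gives. The search covered only flow-through WT and CD45 KO libraries. Flow-through KO and CD45 WT, with 3 libraries each, were too small for it. Lbp was at 30.4 CPM in CD45 KO replicate 1, the highest of that group. Angpt1, uncertain because its exons overlap another gene, was at 5.59 CPM in flow-through WT replicate 3, the lowest of its group, and Akap12 at 244 CPM in flow-through WT replicate 4, the highest of its group.

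In the interaction camera called anti-inflammatory and repair macrophage genes (median -0.22), reactive astrocyte genes (median 0.19) and glutamate and GABA receptor genes (median 0.57). None of these calls held with an estimated correlation, and 100 of 100 splits of the libraries gave at least as many lists. They therefore do not show that the genotype difference differed between the fractions.

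The counts of genes and lists were compared with those from other splits of the same libraries. For genes in the flow-through, the real split was the 1 of 35 with as many as 260, the highest other giving 39. That share of 0.029 is the smallest that 35 splits allow, so chance is unlikely for this count but not excluded. The count also rests on leaving out the library labelled flow-through WT replicate 5, a choice made after the data were seen. The fixed design, which enters that library as labelled, called 0 genes. For genes between the fractions, the real split was the 1 of 100 drawn with as many as 15583, the highest other giving 12346. That is a share of 0.01, so chance is unlikely there too. The list counts of the genotype comparisons and the interaction can arise by chance. For the 9 lists of the flow-through, 29 of 35 splits gave as many, up to 20. For the 11 lists of the CD45 fraction it was 31 of 35, up to 25. For the 3 lists of the interaction it was 100 of 100, up to 21. For the 33 lists between fractions it was 30 of 100, up to 37. Those splits keep part of the fraction difference, 1 of them calling 12346 genes, so they cannot show what chance gives for these lists. A count of 0 is matched by any split, so the splits say nothing about chance for the 0 genes of the CD45 fraction (35 of 35, up to 10) or the 0 genes of the interaction (100 of 100, up to 430). The split with 430 genes kept the flow-through labels and put the 3 CD45 WT libraries and CD45 KO replicate 1 on the KO side. So many genes point to a structure of the samples, whose cause was not tested. The split nearly swaps the CD45 labels, and the genotype difference averaged over both fractions called 2 genes. That average keeps CD45 KO replicate 1 with the KO libraries, unlike the split. It therefore cannot decide whether a difference shared by both fractions accounts for the count.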

How the results depend on the processing

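The alternatives added after the data were seen were those that place the library labelled flow-through WT replicate 5 with CD45 WT, the fit of 14 libraries, the GC and length correction and the treatment of the 2 CD45 libraries that stood apart. Fits that enter that library as labelled follow the design fixed before the data were examined, from which the reported fits depart. All other alternatives were planned. Replicate numbers follow accession order, and no paired analysis was possible because the labels tie no library to an animal. In the flow-through, where 260 genes were called, DESeq2 called 436 (258 of the 260 among them), limma-voom 413 (258) and edgeR without a count filter 629 (260). The library labelled flow-through WT replicate 5 left 0 when entered as labelled, alone or in a fit of all 15 libraries, and a fit of the 14 libraries gave 30, and each of these counts moved. The cause was not tested. Leaving out each library in turn gave 134 (without KO replicate 1) to 287 (without WT replicate 1) genes. RLE scaling (250), upper-quartile scaling (253), a stricter filter (258), limma on the normalized signal (232), an adjusted p under 0.1 (375) and the GC and length correction (191, of which 163 were among the 260) stayed within 1.5 times. The 9 lists called became 0 with an estimated correlation, 0 with fry and 23 with that library as labelled, and 6 to 13 without single libraries, and the cause was not tested. In the CD45 fraction the 0 genes became 10 with DESeq2 and 0 to 1 without single libraries, the 1 being Lbp without CD45 KO replicate 1. They stayed at 0 under the other settings, including the removal of, or a term for, the 2 libraries that stood apart. The 11 lists became 0 with an estimated correlation and 1 with fry. Without the 2 libraries that stood apart 13 lists were called, of which 6 were among the 11, and without single libraries 8 to 13, of which 6 to 8 were. The cause was not tested for these counts. In the interaction the 0 genes became 46 with DESeq2, 15 without a filter, 4 with limma-voom, 1 (Rab15) with the library labelled flow-through WT replicate 5 placed with CD45 WT and 0 to 2 without single libraries (2 without CD45 WT replicate 2 or 3). Its 3 lists became 0 with an estimated correlation, 0 with fry, 25 with that library as labelled and 0 (without CD45 KO replicate 2) to 5 without single libraries. The cause was not tested for the interaction. Between the fractions 13727 to 18604 genes were called under every setting, and the 33 lists became 15 with an estimated correlation, for which the cause was not tested. Upper-quartile scaling lowered the share of higher calls from 48.1% to 40.2%. The counts that moved are printed here, those without single libraries as a range. No value of a gene named by the rule for a comparison reversed to the opposite sign where it was called. Genes named otherwise, such as Nrgn, Gad2 and Rab15 in the flow-through, were not counted here. Of the values of called genes in the flow-through, 424 kept their side of the threshold and 134 did not. Of values of genes not called, 62 in the flow-through, 8 in the CD45 fraction and 15 in the interaction passed the threshold, and 59, 19 and 1 changed sign without passing. All 550 values of called genes between the fractions kept theirs. Mean Epha4 in flow-through WT stayed at 40.8 to 42.2 CPM without single libraries. The CD45 and interaction tests missed many simulated changes of 1.5-fold.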

Other observations

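The tests of the genotype difference averaged over both fractions, of neuroblast genes and of genes with large fitted folds were chosen after the results were seen.

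The flow-through held more than glia. Neuroblast genes were abundant in it, with Dcx, a microtubule protein of migrating neurons, at 101 to 256 CPM, Dlx1 at 79.6 to 143 CPM, Dlx2 at 31 to 49.8 CPM and Sox11 at 71.4 to 139 CPM over the 7 libraries, against at most 1.80 CPM for each in the CD45 libraries. Cd24a, another gene of the set, was not confined to it, at 233 to 426 CPM in the flow-through and 342 to 632 CPM in the CD45 libraries. Exons of Dlx1 and Dlx6os1 overlap other genes, and their values are uncertain. Between genotypes Dcx was at -0.53 (SE 0.17, edgeR adjusted p = 0.255) and Dlx6os1 at -0.43 (SE 0.12, edgeR adjusted p = 0.128), and none of the 12 neuroblast genes passed (camera p = 0.0677 for the list with an estimated correlation). Red cell RNA also took a larger share of the flow-through libraries. The globin genes Hbb-bs, at 5860 to 16800 CPM, and Hba-a1, at 3680 to 10000 CPM, compare with 478 to 1140 CPM and 274 to 627 CPM in the CD45 libraries, and the erythroid list was not called between genotypes in the flow-through (median -0.50, camera adjusted p = 0.114) or in the CD45 fraction (median 0.00, adjusted p = 0.962).

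At 1 day several myeloid genes stood at high levels in the CD45 fraction. S100a9, a calcium-binding protein of neutrophils and monocytes, lay at 1650 to 3820 CPM, Ccr2, the receptor of inflammatory monocytes, at 203 to 572 CPM, and Cx3cr1, of microglia, at 586 to 788 CPM. The neutrophil gene Retnlg lay at 31.7 to 235 CPM. The microglial receptor P2ry12 lay at 42.1 to 95.9 CPM. Lymphocyte genes were scarce, with Cd3e of T cells at 2.97 to 7.05 CPM and Cd79a of B cells at 2.51 to 8.56 CPM. Exons of Cx3cr1, Cd3e and, over a few bases, P2ry12 overlap other genes, and their values are uncertain.

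Averaged over both fractions, the genotype difference called 2 of 18098 genes in edgeR, with 1396 at an unadjusted p under 0.05. Abhd1 fell (log2 fold change -0.66, SE 0.08, adjusted p = 0.013) and Stac2, a gene linked to calcium channels, rose (0.70, SE 0.10, adjusted p = 0.0499). Abhd1 overlaps Preb and is uncertain. The fit treats all libraries as independent, though the labels do not exclude shared animals, in which case these p-values are too small.

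The largest fitted folds among called flow-through genes belonged to predicted models outside the naming rule. The 5 genes with an absolute log2 fold change over 3 were the pseudogenes Gm2792 (5.01, SE 0.57) and Gm49693 (4.34, SE 0.70), which overlap each other on chromosome 17, the pseudogene Gm9347 (-3.76, SE 0.43) on chromosome 7, the predicted gene Gm9008 (-3.46, SE 0.70) on chromosome 6 and the small RNA gene Gm22490 (-3.79, SE 0.86) on chromosome 5. Gm2792 had 69 to 181 counts in the 3 KO and 0 to 6 in the 4 WT flow-through libraries, but 1 to 36 in the 4 KO and 3 to 46 in the 3 WT CD45 libraries. Gm9008 had 0 to 12 counts in KO and 29 to 71 in WT flow-through libraries, and 0 to 18 in KO and 24 to 36 in WT CD45 libraries. Gm22490 had 0 to 3 counts in KO and 7 to 22 in WT flow-through libraries, and 0 to 14 in KO and 20 to 28 in WT CD45 libraries. In the CD45 libraries the counts of Gm9347 and Gm49693 overlapped between genotypes. Such genes can share reads with near-identical copies, so their counts are uncertain. Variants that differ between the animals of the groups may contribute, a hypothesis that was not tested for these genes. The test on the lower genes in the CD45 fraction (exact two-sided permutation p = 0.114) leaves out Gm2792 and Gm49693. It also averages over many genes, so it cannot decide for single ones.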
